A study of Mus musculus with 19 samples.

How the data were processed

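Libraries were made by MARS-seq from polyA RNA of fibroblasts sorted for Col1a1-driven yellow fluorescent protein from the peritoneum of 19 mice, 5 normal, 5 at day 7, 5 at day 28 and 4 at the end stage after injection of ID8 cells. RNA was extracted with a column kit, and the labels state that only RNA of high integrity was used. Each library was 1 biological replicate, and the numbers of the replicates were not read as pairs, since the labels describe separate mice. The authors deposited raw counts per gene and library, per the file headers, and whole numbers were found in every column. The authors also deposited a normalized signal, counts divided by 1 size factor per library, which the values bore out to rounding at 2 decimals, and which was used here for that check alone. The authors' deposited table gives a log2 fold change per gene for 6 pairwise comparisons. The authors' deposited p-values are unadjusted and adjusted over genes. The other deposited values are the authors' thresholds, an adjusted p of at most 0.1, an absolute log2 fold change of at least 0.58 and a highest count of at least 30. The submitters' notes name DESeq2 and the genome build GRCm39, without versions. The aligner, the counting tool, the annotation and the treatment of molecular identifiers are not given in the sources used here, so reads shared by near-identical paralogs, such as the globin genes Hba-a1, Hbb-bs and Hbb-bt, leave their counts uncertain.

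The table held 12799 genes, of which 22 had 0 counts in every library, and 3 symbols were shared by more than 1 gene. Total counts ran from 66061 to 2449339, and 3 counts, the limit that a count of 0 allows, corresponded to 45.4 CPM in the shallowest library and 1.22 in the deepest. Floors cover counting error only. Genes were filtered with filterByExpr at a minimum count of 10, close to 32.8 CPM, which left 5980. The common biological coefficient of variation was 0.334, and TMM factors ran from 0.949 to 1.099. CPM use TMM-scaled library sizes, and marker sums use library totals. Genes were tested with edgeR 4.0.16 (TMM, robust dispersion and robust quasi-likelihood fit, quasi-likelihood F test) in 1 model of the 4 groups without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05, in R 4.3.3. The comparisons were each of the 3 stages with normal, day 28 with day 7, end stage with day 28, and the 3 stages jointly. The SE of a log2 fold change was its size over the square root of F. Genes and list members are called by edgeR unless another tool is named. Principal components used log2 CPM with a prior count of 2 over 500 genes.

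Of 39 gene lists, 30 had at least 5 tested members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, with an estimated correlation as an alternative and with fry, which asks whether the genes of a list move on balance one way. Lists of erythrocyte, sex-linked, macrophage, T and NK, B, neutrophil, adipocyte, Schwann and epithelial genes had too few tested members and are given as sums, or for the sex-linked list as Xist. Summed counts of 17 lists in 5 comparisons were compared by two-sided exact permutation tests, adjusted over 85 tests. The model, the lists, the comparisons and the rule for named genes were chosen before the data were examined. Genes named were, first, up to 8 higher and 8 lower called genes of each comparison with normal, and up to 5 and 5 of each pair of successive stages, by size of log2 fold change among genes with a mean of at least 20 CPM and no overlap between the groups, without predicted genes. Second came members of each list in order of p, at most 4, and last 12 genes followed in every comparison, Col1a1, Acta2, Il6, Cxcl12, Ccl2, Cd74, H2-Ab1, Saa3, Lcn2, Pdgfra, Tgfb1 and Cd274.

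The steps were tested on simulated data of the same depths, with 200 changed genes in each of 5 comparisons. The complement list was raised 2-fold in addition. Of genes changed 2-fold, 18% to 24% were recovered, and of genes changed 4-fold, 73% to 86%. Alternatives were DESeq2 1.42.0, limma-voom with quality weights, DESeq2 size factors, library size scaling, no filter and a stricter filter, the 2 groups alone, the replicate number as a block, a log2 fold change of at least 1, and each library left out in turn. Added after the data were seen were the authors' thresholds, thinning to 200000 counts, leaving out 3 libraries under 150000 counts, the removal of the ribosomal RNA gene Rn18s-rs5 (0.216% to 4.65% of counts), and the immediate-early sum or the within-group component as a covariate. Sharing of normal libraries between comparisons was assessed with 20 simulations of unchanged groups and 10 splits of the normal libraries. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. A result withheld for evaluation is not reported here. It is part of the counts of called genes and the tests of lists, but not of the sensitivity rows for single genes or the flagged differences between stages.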

Results

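Fibroblasts of the mouse peritoneum were compared before and during the growth of ovarian carcinoma in the peritoneal cavity. The fibroblasts carried a yellow fluorescent protein driven by Col1a1, the gene of a fibrillar collagen chain, and were sorted from dissociated peritoneum. Tumour-bearing mice had received ID8 cells, a mouse ovarian carcinoma line marked here with tdTomato, by intraperitoneal injection in 200 µL of PBS. Control mice had received PBS alone. The 19 libraries came from 19 mice and fell into 4 groups, with 5 normal, 5 day 7, 5 day 28 and 4 end stage libraries. The day of the end stage is not stated in the labels. The series title names stromal and immune interactions in peritoneal metastasis as the subject. The groups allow the fibroblast transcriptome to be followed from the normal peritoneum to early, later and final tumour growth.

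The RNA libraries were made by MARS-seq, a protocol for small amounts of RNA, and were shallow and unequal. Total counts ran from 66061 in day 28 replicate 1 to 2449339 in end stage replicate 4, a ratio of 37.1. The median total was 304626 in normal, 313890 in day 7, 172313 in day 28 and 378400 in end stage libraries. Of the 12799 genes in the table, 5980 had enough counts to be tested, and these held 93.2% to 94.9% of the counts of each library. In a principal component analysis of 500 variable genes, the first component (21.9% of the variance) set day 28 replicate 1, the shallowest library, apart at −46.6 against −10.9 to 12.8 for the other libraries. The first component had a Spearman correlation of 0.79 with total counts. The second component (13.9%) set apart day 28 replicate 2 at 35.3. A component computed after removal of the group means held 28% of the within-group variance of 1751 abundant genes. With the group means removed, each group must have libraries on both sides of 0, so a parting within each group is built in. Below 0 on the component lay 10 libraries, namely normal replicates 1 and 3, day 7 replicates 1, 2 and 5, day 28 replicates 1, 3 and 5, and end stage replicates 2 and 3. The labels name no batch that follows this division. Log2 fold changes are given ± SE, and levels as mean ± SD in CPM scaled by TMM.

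**Figure D1:**
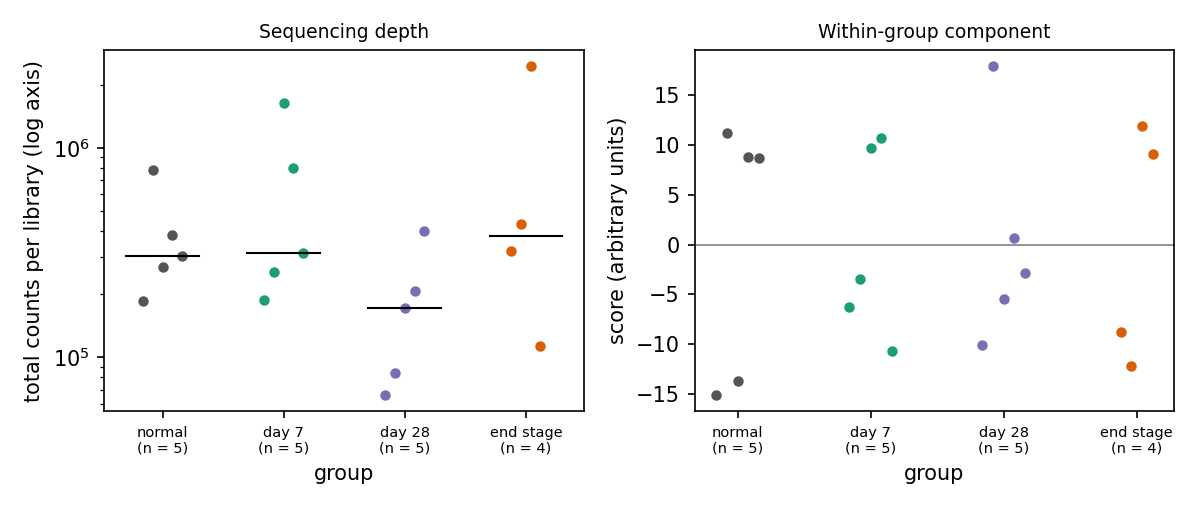
Total counts per library (left, logarithmic axis) and position on the within-group component (right, arbitrary units), with 1 point per library in the 4 groups and bars at the group medians on the left. Totals span 66061 to 2449339, and 10 libraries lie below 0 on the component. Every group spans 0 because its mean was removed.

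The comparison of day 7 with normal fibroblasts asked what changed early in tumour growth. Ret, the receptor tyrosine kinase of the GDNF family of ligands, rose from 9.03 ± 2.07 CPM (SD, n = 5) to 54.9 ± 21.8 CPM (SD, n = 5), a log2 fold change of 2.54 ± 0.51. A floor of 3 counts corresponds to 3.82 to 16.1 CPM in the normal libraries, so the size of this rise is uncertain. Lamb1, a laminin chain of basement membranes, rose from 198 ± 13.4 CPM (SD, n = 5) to 413 ± 74.7 CPM (SD, n = 5), with a log2 fold change of 1.06 ± 0.21. The predicted gene Gm4366, outside the rule for named genes and chosen after its values were seen, fell by 2.04 (SE 0.42) on the log2 scale, from 129.9 ± 54.8 CPM (SD, n = 5) to 31.7 ± 14.6 CPM (SD, n = 5). These were the 3 genes called of 5980 tested, 2 higher and 1 lower, each with an adjusted p of 0.0455 (edgeR quasi-likelihood test, Benjamini-Hochberg) and no overlap between the 5 libraries of each group.

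Basement membrane genes stood higher at day 7 as a list. Of 12 tested members, 11 had a positive log2 fold change and 1 was called over all genes, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.53e-06, estimated-correlation adjusted p = 0.135). Lamb1 was followed by Lama4 at 0.72 ± 0.27 and Lamc1 at 0.57 ± 0.24, 2 further laminin chains that were not called. The list of fibrillar collagens and other structural matrix genes was also higher, with 17 of 22 members positive, 0 higher and 0 lower over all genes, and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000442, estimated-correlation adjusted p = 0.326). Its members with the smallest p were Fn1, fibronectin, at 1.02 ± 0.26, Postn, periostin, at 1.39 ± 0.40, and, on the lower side, the thrombospondin Thbs2 at -0.79 ± 0.25. The inflammatory fibroblast list was higher with 13 of 16 members positive and none called by either adjustment (camera adjusted p = 0.0221, estimated-correlation adjusted p = 0.3). Ccl11, an eosinophil chemokine, had the smallest p, at 0.88 ± 0.33. The 6 tested mitochondrially encoded genes were all positive and none was called by either adjustment (camera adjusted p = 8.34e-07, estimated-correlation adjusted p = 0.3). Among them mt-Cytb was at 0.82 ± 0.33. Cytosolic ribosomal protein genes were higher with 26 of 41 positive, 0 higher and 0 lower over all genes, and 2 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00936, estimated-correlation adjusted p = 0.875). Rpl32 had the smallest p, at 0.86 ± 0.24.

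Markers of mesothelial cells, the lining cells of the peritoneum, were lower at day 7. All 11 tested markers had a negative log2 fold change, none was called over all genes, and 3 were lower adjusted over the list alone (camera adjusted p = 8.24e-06, estimated-correlation adjusted p = 0.3). They included Rspo1 at -0.86 ± 0.28, Msln, mesothelin, at -1.40 ± 0.49, and Cldn15 at -0.95 ± 0.36. The summed mesothelial markers were 558 ± 290.1 CPM at day 7 (SD, n = 5) and 928 ± 440.1 in normal libraries, or 733 ± 83.9 (SD, n = 4) without normal replicate 1, which stood at 1704. This difference was not called (two-sided exact permutation p = 0.111, adjusted p = 0.472 over 85 sums). Of the 12 genes followed in every comparison, 10 were tested and none was called at day 7. Their log2 fold changes were 0.34 ± 0.36 for Col1a1, -1.27 ± 0.45 for the smooth muscle actin Acta2, 0.77 ± 0.60 for Il6, 0.36 ± 0.25 for Cxcl12 and 0.47 ± 0.67 for Ccl2. They were -0.85 ± 0.49 for Cd74, 0.81 ± 0.95 for H2-Ab1 (−1.65 with limma-voom), -0.58 ± 0.95 for the acute-phase gene Saa3, -0.30 ± 0.31 for Pdgfra and -0.08 ± 0.42 for Tgfb1. An unadjusted p under 0.05 was reached by 208 genes, against 299 expected by chance. No overlap between the groups was seen for 0.79% of genes, the share chance gives. The authors' deposited table holds 4 higher and 2 lower genes at an adjusted p under 0.05.

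The 3 calls at day 7 rested on small margins. With library size scaling, the 2 groups alone, the replicate block, thinning to 200000 counts, the shallow libraries left out or the immediate-early sum as a covariate, 0 genes were called, and 0 were called without any 1 of normal replicates 1 to 5, day 7 replicates 1 to 5, day 28 replicates 1, 2 and 3, or end stage replicates 2, 3 and 5. The inflammatory fibroblast call was lost without normal replicate 1 or day 7 replicate 3 or 4, and the ribosomal call without normal replicate 1 or 5 or day 7 replicate 3 or 4. The 5 lists called higher became 3 without normal replicate 1, day 7 replicate 3 or day 7 replicate 4, and 9 without a filter, the 1 called lower became 2 without day 7 replicate 1 or without a filter, limma-voom called 7 genes lower and DESeq2 2, and without a filter 1 gene was higher and 2 lower.

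The comparison of day 28 with normal fibroblasts asked what differed at the later stage. By camera with a preset correlation, interferon-stimulated genes stood higher as a list, and genes of NF-kB signalling and the immediate-early response stood lower. None of the 3 lists was called with an estimated correlation (adjusted p = 0.479, 0.657 and 0.787) or with fry (0.499, 0.499 and 0.582), and the interferon call was lost without day 28 replicate 3 or 5. The NF-kB call was lost without normal replicate 4 or 5 or day 28 replicate 1, 2 or 4, and the immediate-early call without normal replicate 4 or 5, day 7 replicate 1 or day 28 replicate 3 or 4. Usp18, a protease that removes the interferon-induced protein Isg15 from its targets, was at 23.6 ± 5.52 CPM (SD, n = 5) in normal and 65.2 ± 44.5 CPM (SD, n = 5) in day 28 libraries, a log2 fold change of 1.59 ± 0.48 that was not called over all genes (adjusted p = 0.572, edgeR). No gene passed: 0 of 5980 genes were called higher and 0 lower by edgeR's quasi-likelihood test (lowest adjusted p = 0.287), with 422 genes at an unadjusted p under 0.05, where DESeq2 and limma-voom called 0, with 639 and 579 genes at an unadjusted p under 0.05. The authors' deposited table likewise holds 0 higher and 0 lower genes at an adjusted p under 0.05. Groups had no overlap for 1.05% of genes, against 0.79% by chance.

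Of 16 tested interferon-stimulated genes, 12 had a positive log2 fold change, with 0 higher and 0 lower over all genes and 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0258, estimated-correlation adjusted p = 0.479). After Usp18 came Irf9, a component of the interferon signalling complex, at 0.82 ± 0.34, and the GTPase Igtp at 1.02 ± 0.43. Genes of MHC class I presentation were higher with 10 of 13 positive and none called by either adjustment (camera adjusted p = 0.0258, estimated-correlation adjusted p = 0.479). H2-T22 was at 0.68 ± 0.28 and the peptide loading factor Tapbp at 0.65 ± 0.29. The hypoxia and glycolysis list was higher with 12 of 15 positive and none called by either adjustment (camera adjusted p = 0.0258, estimated-correlation adjusted p = 0.479). Ldha, a lactate dehydrogenase subunit, had the smallest p, at 0.61 ± 0.26. Basement membrane genes were higher with 10 of 12 positive and none called by either adjustment (camera adjusted p = 0.0403, estimated-correlation adjusted p = 0.479). Col18a1 had the smallest p, at 0.82 ± 0.31. The NF-kB and acute-phase list was lower, with 11 of 15 negative and none called by either adjustment (camera adjusted p = 0.0258, estimated-correlation adjusted p = 0.657). Nfkb1 had the smallest p, at -1.27 ± 0.46. Genes of the unfolded protein response were lower with 15 of 17 negative and none called by either adjustment (camera adjusted p = 0.0403, estimated-correlation adjusted p = 0.479). Hsp90b1, a chaperone, had the smallest p, at -0.73 ± 0.35. The immediate-early and dissociation stress list was lower with 19 of 25 negative, 0 higher and 0 lower over all genes, and 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0403, estimated-correlation adjusted p = 0.787). Its leading members were the transcription factors Fosb at -0.80 ± 0.23 and Egr1 at -0.61 ± 0.21. The 5 tested skeletal muscle markers were all negative, with 1 lower adjusted over the list alone and none over all genes (camera adjusted p = 0.0278, estimated-correlation adjusted p = 0.479). Tnni2 had the smallest p, at -2.82 ± 0.85.

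The genes followed throughout included the chemokine Ccl2 at 11.8 ± 12.8 CPM (SD, n = 5) against 64.0 ± 58.2 CPM (SD, n = 5), a log2 fold change of -1.96 ± 0.92, and the cytokine Il6 at -1.40 ± 0.85, neither of which was called. The others were Col1a1 at 0.24 ± 0.36, Acta2 at -0.04 ± 0.46, Cxcl12 at 0.45 ± 0.26, Cd74 at 0.30 ± 0.50, H2-Ab1 at 1.48 ± 0.95, Saa3 at 0.03 ± 0.99, Pdgfra at -0.08 ± 0.33 and Tgfb1 at 0.13 ± 0.47, none of them called. The unfolded protein call was lost without normal replicate 2, 4 or 5, day 7 replicate 1 or day 28 replicate 1, 2, 3 or 5, and the basement membrane call without normal replicate 3, 4 or 5, day 7 replicate 1 or day 28 replicate 1 or 2. The MHC class I call was lost without normal replicate 5 or day 28 replicate 3 or 4, and the skeletal muscle call, tested in 12 of the 19 fits, without day 28 replicate 2, 4 or 5. The 4 lists called lower became 0 without normal replicate 4 or 5 or with the immediate-early sum as a covariate, 1 without day 7 replicate 1, day 28 replicate 2 or day 28 replicate 3, and 2 without day 28 replicate 4 or 5 or with thinning. The 4 called higher became 2 without normal replicate 5 or with thinning and 0 with that covariate, and without day 28 replicate 5 edgeR called 1 gene lower.

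The comparison of successive stages, day 28 against day 7, gave no called gene with edgeR. Postn, at 475 ± 182 CPM (SD, n = 5) at day 7, was at 144 ± 59.6 CPM (SD, n = 5) at day 28, a log2 fold change of -1.66 ± 0.43. Fn1 was at -0.78 ± 0.26 and Lamb1 at -0.86 ± 0.22. These 3 were named for their rise in the same day 7 libraries, so a negative change was expected from that choice. None of these was called over all genes (adjusted p = 0.326, 0.423 and 0.319, edgeR). In the interferon list Oasl2 was at 1.24 ± 0.36 and Usp18 at 1.25 ± 0.45, also not called over all genes. edgeR's quasi-likelihood test called 0 genes (lowest adjusted p = 0.319), with 538 at an unadjusted p under 0.05, where DESeq2 called 0 with 810 at an unadjusted p under 0.05 and limma-voom 23 higher and 9 lower. The authors' deposited table holds 0 higher and 1 lower gene at an adjusted p under 0.05. No overlap was found for 1.34% of genes, against 0.79% by chance.

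Lists called lower at day 28 than at day 7 were 5, and none was called higher. The day 7 and day 28 libraries also served the comparisons with normal, so a list called in both was not tested independently. Cytosolic ribosomal protein genes had 34 of 41 negative, with none called by either adjustment (camera adjusted p = 0.000201, estimated-correlation adjusted p = 0.519). Rps20 had the smallest p, at -0.76 ± 0.23. The mitochondrially encoded genes were all 6 negative and none called by either adjustment (camera adjusted p = 0.000765, estimated-correlation adjusted p = 0.519). Here mt-Cytb was at -0.86 ± 0.34. The NF-kB and acute-phase list had 11 of 15 negative and none called by either adjustment (camera adjusted p = 0.0220, estimated-correlation adjusted p = 0.519). Tnfaip6 had the smallest p, at -0.94 ± 0.39. The unfolded protein response had 13 of 17 negative and none called by either adjustment (camera adjusted p = 0.0304, estimated-correlation adjusted p = 0.519). Hsp90b1 had the smallest p, at -0.88 ± 0.35. Skeletal muscle markers were all 5 negative, with 0 higher and 2 lower adjusted over the list alone and none over all genes (camera adjusted p = 0.00574, estimated-correlation adjusted p = 0.519). Tnnt3 had the smallest p, at -2.64 ± 0.79. The matrix structure list itself was not called (camera adjusted p = 0.203), with 1 higher and 2 lower adjusted over the list alone, and neither was the interferon list (camera adjusted p = 0.0669), with 4 higher and 1 lower adjusted over the list alone. Log2 fold changes of the genes followed throughout were -2.16 ± 0.80 for Il6, -2.43 ± 0.90 for Ccl2, 1.23 ± 0.49 for Acta2, 1.16 ± 0.53 for Cd74 and 0.67 ± 0.91 for H2-Ab1. They were -0.10 ± 0.36 for Col1a1, 0.09 ± 0.26 for Cxcl12, 0.61 ± 1.04 for Saa3, 0.22 ± 0.33 for Pdgfra and 0.21 ± 0.46 for Tgfb1, and none was called. The NF-kB call was lost without day 7 replicate 3 or 4 or day 28 replicate 1 or 4, the unfolded protein call without day 7 replicate 3 or 4 or day 28 replicate 1 or 5, and the skeletal muscle call, tested in 12 of the 19 fits, without day 28 replicate 4. The 5 lists lower became 2 without day 7 replicate 4, 3 without day 7 replicate 3, day 28 replicate 1 or day 28 replicate 4, and 8 without day 28 replicate 2. Lists were also called higher under several settings, up to 5 with a stricter filter, and 1 to 4 when any 1 of normal replicates 1, 2, 4 and 5, day 7 replicates 1, 2, 3 and 5, day 28 replicates 1, 2, 3 and 5, or end stage replicates 2 and 3 was left out.

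**Figure D2:**
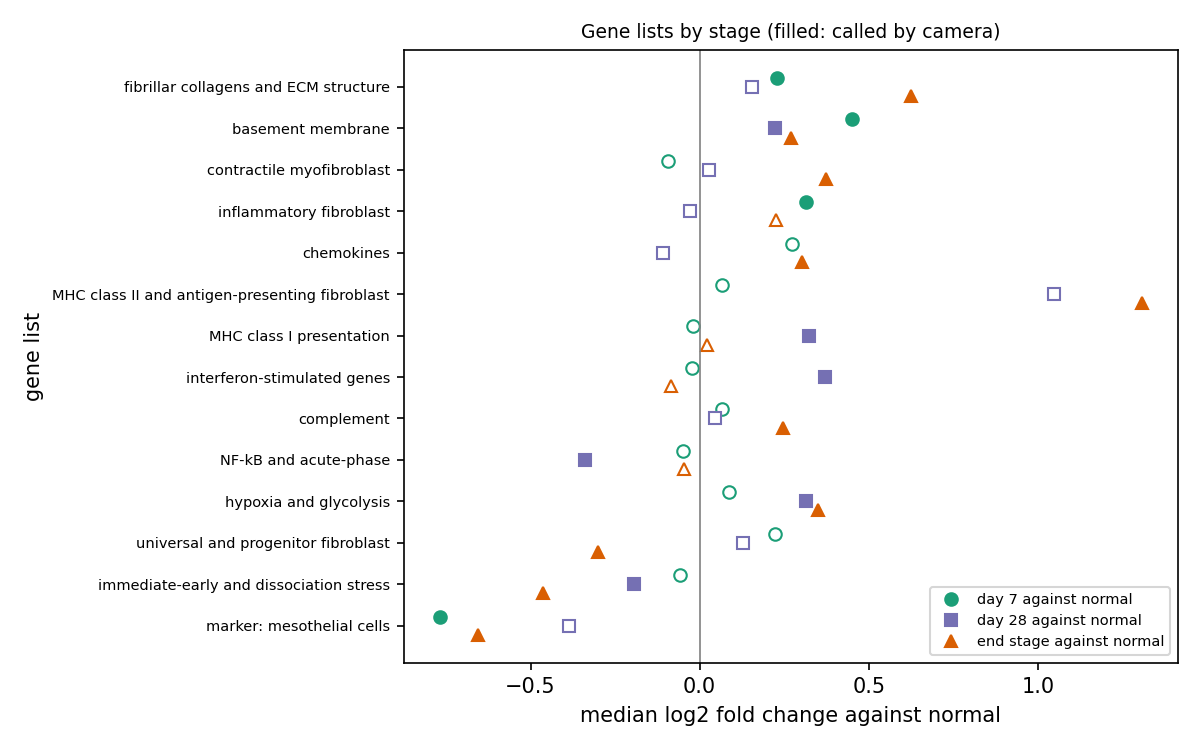
Median log2 fold change of the members of 14 gene lists at day 7, day 28 and end stage against normal, with 1 row per list. Filled points mark lists called by camera with a preset correlation, and open points lists not called. The matrix structure list lies at 0.23, 0.16 and 0.62.

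At the end stage, the comparison with normal fibroblasts showed the most called genes of the 3 stages. Slc16a3, which exports lactate from glycolytic cells, rose 8.26-fold from 12.4 ± 10.2 CPM (SD, n = 5) to 86.9 ± 23.7 CPM (SD, n = 4), a log2 fold change of 3.04 ± 0.58. Its normal level lay near the floor of 3 counts, 3.82 to 16.1 CPM in those libraries, so the size of the rise is uncertain. Col8a1, a network-forming collagen chain, rose by 2.60 ± 0.42 from 40.3 ± 14.0 CPM (SD, n = 5) to 243 ± 180.0 CPM (SD, n = 4), with 513 CPM in replicate 4 and 164 in the next library, and by 1.90 without replicate 4. F2r, the thrombin receptor, rose by 2.29 ± 0.35 from 56.9 ± 14.5 CPM (SD, n = 5) to 269 ± 137 CPM (SD, n = 4). The chemokine Cxcl14 rose by 1.70 ± 0.25 from 250.0 ± 69.2 CPM (SD, n = 5) to 806 ± 195 CPM (SD, n = 4). Fmo2, a flavin monooxygenase, fell by 1.80 (SE 0.39) on the log2 scale, from 190.2 ± 45.1 CPM (SD, n = 5) to 57.4 ± 11.8 CPM (SD, n = 4). Of 5980 genes, 19 were higher and 5 lower (edgeR quasi-likelihood test, Benjamini-Hochberg).

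**Figure D3:**
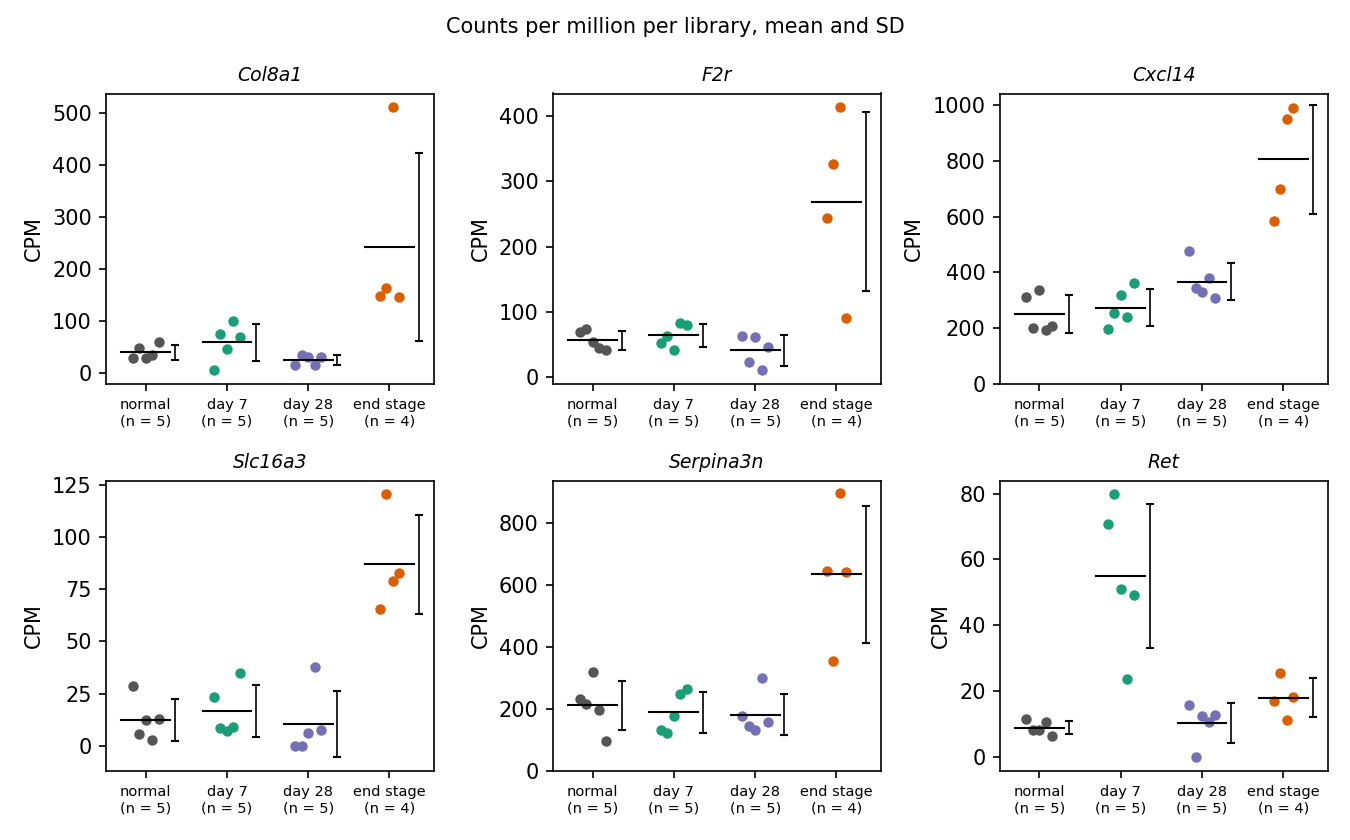
CPM of Col8a1, F2r, Cxcl14, Slc16a3, Serpina3n and Ret in each library of the 4 groups, with 1 point per library, a bar at the group mean and whiskers of 1 SD. The end stage libraries lie above all normal libraries for the first 5 genes, and the day 7 libraries above all normal libraries for Ret.

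Other genes that rose were the transcription factor Runx1 by 2.77 ± 0.58, the cytochrome P450 Cyp1b1 by 2.41 ± 0.53, the protease inhibitor Serpina3n by 1.60 ± 0.30 and the WNT receptor Fzd1 by 1.53 ± 0.34. Without end stage replicate 4 Runx1 was at 2.00 and Cyp1b1 at 1.68, neither of them called. Normal levels were 12.26 ± 9.43 CPM for Runx1 and 16.22 ± 7.62 CPM for Cyp1b1 (SD, n = 5). These lay near the floor of 3 counts, 3.82 to 16.1 CPM in normal libraries, so the sizes of both rises are uncertain. Log2 fold changes of the other genes that fell were -1.14 ± 0.25 for the cell cycle inhibitor Cdkn1a, -1.09 ± 0.24 for Fosb and -1.07 ± 0.24 for Plpp3, a phosphatase of lipid phosphates. Adjusted p ran from 0.000365 for Cxcl14 to 0.0293 for Plpp3 among these genes, and none of them overlapped between the 4 end stage and 5 normal libraries. Gm4366, chosen after its values were seen, was the fifth gene lower at -2.24 ± 0.46. Also chosen after their values were seen, Mgp, matrix Gla protein, rose by 2.21 ± 0.45 from 3625 ± 1709 CPM (SD, n = 5) to 16770 ± 8679 CPM (SD, n = 4). Hbb-bs, a beta-globin gene, rose by 3.00 ± 0.60, both with overlap between the groups. Hbb-bs has a near-identical neighbour, Hbb-bt, so its value is uncertain.

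The list of fibrillar collagens and other structural matrix genes rose at the end stage. Of 22 members, 18 had a positive log2 fold change, 3 were called higher over all genes and 5 were higher adjusted over the list alone (camera adjusted p = 7.76e-10, estimated-correlation adjusted p = 0.0864). The called members were Col8a1, the proteoglycan Bgn at 1.14 ± 0.22 and elastin, Eln, at 1.26 ± 0.27, followed by Postn at 1.49 ± 0.42, which was not called over all genes. Contractile myofibroblast genes were higher with 9 of 13 positive, 0 higher and 0 lower over all genes by edgeR, and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00442, estimated-correlation adjusted p = 0.0864). DESeq2 called the member Ccn2. Actn1 was at 1.25 ± 0.35, and Ccn2, connective tissue growth factor, at 2.09 ± 0.49, or 0.82 without end stage replicate 4, which had 2631 CPM against 251 to 596 in the other end stage libraries. Basement membrane genes were higher with 9 of 12 positive, 0 higher and 0 lower over all genes, and 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0322, estimated-correlation adjusted p = 0.279). Col4a2 was at 1.01 ± 0.27 and Col4a1 at 0.87 ± 0.26. The chemokine list was higher with 7 of 8 positive, 1 called higher over all genes and 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00256, estimated-correlation adjusted p = 0.0864). After Cxcl14 came Cxcl12 at 0.67 ± 0.27. Complement genes were higher with 8 of 11 positive, 1 called over all genes and 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0136, estimated-correlation adjusted p = 0.231). Factor B, Cfb, rose by 1.39 ± 0.29, and C4b was at 1.06 ± 0.34 and C1qa at 1.83 ± 0.60. MHC class II genes were higher with 4 of 5 positive, 0 higher and 0 lower over all genes, and 2 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00359, estimated-correlation adjusted p = 0.231). In that list the invariant chain Cd74 went from 35.7 ± 18.4 CPM (SD, n = 5) to 110.8 ± 60.4 CPM (SD, n = 4), a log2 fold change of 1.63 ± 0.45. It was not called over all genes (adjusted p = 0.112, edgeR), and H2-Eb1 was at 1.41 ± 0.55.

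Hypoxia and glycolysis genes were higher with 10 of 15 positive, 1 called over all genes and 2 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00442, estimated-correlation adjusted p = 0.231). Slc16a3 was followed by Ldha at 0.88 ± 0.26. Nuclear-encoded oxidative phosphorylation genes were higher with 27 of 34 positive and none called by either adjustment (camera adjusted p = 0.0143, estimated-correlation adjusted p = 0.231). Cox4i1 had the smallest p, at 0.55 ± 0.25. Cytosolic ribosomal protein genes were higher with 35 of 41 positive and none called by either adjustment (camera adjusted p = 0.00110, estimated-correlation adjusted p = 0.320). Rpl32 had the smallest p, at 0.54 ± 0.26. The immediate-early and dissociation stress list was lower, with 21 of 25 negative, 1 called over all genes and 0 higher and 5 lower adjusted over the list alone (camera adjusted p = 1.22e-06, estimated-correlation adjusted p = 0.231). Fosb was followed by Egr1 at -0.78 ± 0.23 and Zfp36 at -0.82 ± 0.25. Its summed counts were 27738 ± 6007 CPM at the end stage (SD, n = 4) and 39358 ± 6490 in normal libraries (exact permutation p = 0.0317, adjusted p = 0.386). Progenitor fibroblast genes were lower with 17 of 23 negative, 0 higher and 0 lower over all genes by edgeR, and 0 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00442, estimated-correlation adjusted p = 0.231). Cd34, which DESeq2 called, was at -0.87 ± 0.23, Scara5 at -0.87 ± 0.28 and Sema3c at -1.13 ± 0.37. Cholesterol and lipid synthesis genes were lower with 8 of 11 negative, 0 higher and 0 lower over all genes, and 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0197, estimated-correlation adjusted p = 0.231). Scd2, a desaturase, had the smallest p, at -0.99 ± 0.32. Mural cell and smooth muscle markers were higher with 5 of 6 positive, 0 higher and 0 lower over all genes, and 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00110, estimated-correlation adjusted p = 0.0864). Notch3 was at 2.04 ± 0.55 and Pdgfrb at 0.58 ± 0.23. Mural sums moved with the matrix and contractile lists, at 878 ± 187 CPM (SD, n = 4) against 567 ± 103 in normal libraries (exact permutation p = 0.0238, adjusted p = 0.386). Mesothelial markers were lower with 9 of 11 negative, 0 higher and 0 lower over all genes, and 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00636, estimated-correlation adjusted p = 0.288). Rspo1 had the smallest p, at -1.02 ± 0.31, followed by Cldn15 at -1.20 ± 0.39.

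With fry, 4 lists moved higher on balance at the end stage, the matrix structure and contractile lists (adjusted p = 0.0453 and 0.0466), mural markers (0.0453) and the cell cycle list (0.0453), which camera did not call (adjusted p = 0.136). Not called at the end stage were the ECM remodelling enzymes (camera adjusted p = 0.0619), inflammatory fibroblast (0.132), MHC class I (0.515), interferon (0.631), NF-kB (0.591), immune checkpoint (0.200) and TGF-beta response (0.157) lists. The growth factor (0.304), unfolded protein (0.808), WNT and BMP (0.696), retinoid (0.591), antioxidant (0.591), mitochondrial (0.567), endothelial (0.136) and skeletal muscle (0.0705) lists were not called either. In the ECM enzyme list the collagen cross-linking enzyme Lox was at 1.12 ± 0.27 and the protease inhibitor Timp1 at 1.97 ± 0.47. Neither was called over all genes by edgeR, while DESeq2 called both. By edgeR 3 members were higher and 1 lower adjusted over the list alone.

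Of the genes followed throughout, Saa3 went from 27.2 ± 25.3 CPM (SD, n = 5) to 260.3 ± 258 CPM (SD, n = 4), a log2 fold change of 3.41 ± 0.83 that was not called over all genes (adjusted p = 0.103, edgeR). DESeq2 called Saa3 in this comparison. None of the others was called over all genes, with log2 fold changes of 0.67 ± 0.38 for Col1a1, 0.62 ± 0.45 for Acta2, 0.32 ± 0.66 for Il6, 0.21 ± 0.72 for Ccl2 (−1.01 without end stage replicate 4), 0.91 ± 0.97 for H2-Ab1, -0.89 ± 0.34 for Pdgfra and 0.92 ± 0.42 for Tgfb1. Lcn2 and Cd274 were too low to be tested. Lcn2 was at 5.58 ± 7.13 CPM (SD, n = 5) in normal and 29.9 ± 31.1 CPM (SD, n = 4) in end stage libraries and had 0 counts in all 5 day 28 libraries. Cd274, which encodes PD-L1, was at 3.98 ± 1.19 CPM (SD, n = 5) and 2.16 ± 1.49 CPM (SD, n = 4). A floor of 3 counts corresponds to 1.22 to 45.4 CPM over the libraries, and Lcn2 ran from 2.57 to 73.3 CPM in the end stage libraries. An unadjusted p under 0.05 was reached by 421 genes, against 299 expected by chance. Of the tested genes 3.18% had no overlap, against 1.59% by chance. The authors' deposited table holds 28 higher and 12 lower genes at an adjusted p under 0.05.

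The end stage count moved with single libraries and with settings. Leaving out a library gave 3 higher and 0 lower without normal replicate 4, 8 and 2 without normal replicate 3, 6 and 1 without end stage replicate 4, 33 and 8 without end stage replicate 2, 12 higher without normal replicate 1, 10 higher without normal replicate 5, 2 lower without normal replicate 2 and 10 lower without end stage replicate 3, and of the 24 genes Cxcl14, F2r and Col8a1 were called in all 19 such fits, while the other called genes named above were called in 11 (Hbb-bs) to 18 (Slc16a3 and Bgn). Of the end stage list calls, the basement membrane call was lost without normal replicate 4 or 5 or end stage replicate 4 or 5, the cholesterol call without normal replicate 3 or 5 or end stage replicate 4, and the mesothelial call without normal replicate 1 or end stage replicate 2 or 3. The progenitor call was lost without end stage replicate 4 or 5, the complement call without normal replicate 5 or day 28 replicate 3, the oxidative phosphorylation call without normal replicate 1 or end stage replicate 4, the ribosomal call without end stage replicate 4 and the hypoxia call without end stage replicate 3. Other settings gave 49 and 23 with the within-group component as a covariate, 32 and 16 with DESeq2, 32 and 18 with limma-voom, 30 and 12 at the authors' thresholds, 29 higher without a filter, 10 lower with the replicate block, 2 lower with the 2 groups alone, 12 and 2 with thinning, and 1 and 0 with the immediate-early sum as a covariate, and the 10 lists called higher became 18 without a filter and 6 with that covariate, which left 2 of the 4 lower.

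From day 28 to the end stage, the last pair of successive stages, 23 of 5980 genes were called higher and 1 lower (edgeR). Col8a1 rose from 25.9 ± 9.17 CPM (SD, n = 5) to 243 ± 180 (SD, n = 4), a log2 fold change of 3.24 ± 0.49. Without end stage replicate 4 it was at 2.52. F2r rose by 2.79 ± 0.40. Slc16a3 was at 2.78 ± 0.64, of uncertain size, since it was at 3.94 without day 28 replicate 4, which had 37.8 CPM against 0 to 7.65 in the other day 28 libraries. Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, was at 2.55 ± 5.70 CPM (SD, n = 5) at day 28 and 60.9 ± 44.3 CPM (SD, n = 4) at the end stage. With 0 counts in 4 of the 5 day 28 libraries, where a floor of 3 counts reaches 45.4 CPM, the size of its rise is uncertain: the log2 fold change was 3.60 ± 0.69, 7.95 without day 28 replicate 5 and 2.82, not called, without end stage replicate 4. The acid phosphatase Acp5 rose by 2.34 ± 0.54, or by 3.02 without day 28 replicate 4. Its day 28 level, 11.35 ± 10.43 CPM (SD, n = 5), was under the highest of those floors, so the size of its rise is uncertain too. Lox rose by 2.16 ± 0.30, from 140.5 ± 44.8 CPM (SD, n = 5) to 598 ± 336 CPM (SD, n = 4). Cd34, a marker of progenitor fibroblasts, fell by 1.00 (SE 0.23) on the log2 scale, from 2001 ± 245 CPM (SD, n = 5) to 997 ± 384 CPM (SD, n = 4). The genes named here were all called, with adjusted p from 0.000126 for Lox to 0.041 for Acp5 and no overlap between the groups. Of the 19 fits with 1 library left out, Lox, F2r and Col8a1 were called in 19, Tnfrsf11b in 18, Slc16a3 and Cd34 in 12 and Acp5 in 8.

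The matrix structure list was higher at the end stage than at day 28 by camera with a preset correlation alone, with 17 of 22 members positive, 3 called over all genes and 6 higher adjusted over the list alone (camera adjusted p = 9.27e-05, estimated-correlation adjusted p = 0.338, fry adjusted p = 0.0794). Bgn and Eln rose with Col8a1 by 1.03 ± 0.22 and 1.15 ± 0.27, called in 15 and 5 of the 19 fits. Chemokines were higher with 7 of 8 positive, 1 called over all genes and 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0168, estimated-correlation adjusted p = 0.338). Cxcl14 rose by 1.15 ± 0.25, called in 13 of them. The NF-kB and acute-phase list was higher with 11 of 15 positive, 0 higher and 0 lower over all genes by edgeR, and 2 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0122, estimated-correlation adjusted p = 0.400). The interleukin 1 receptor Il1r1 was at 1.53 ± 0.41 and Saa3, which DESeq2 called, at 3.37 ± 0.91. TGF-beta response genes were higher with 13 of 16 positive, 1 called over all genes and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0168, estimated-correlation adjusted p = 0.338). Ccn2 was at 2.41 ± 0.52 with overlap between the groups, was called in 3 of 19 fits with 1 library left out, and stood at 1.13, not called, without end stage replicate 4. Oxidative phosphorylation genes were higher with 24 of 34 positive and none called by either adjustment (camera adjusted p = 0.0118, estimated-correlation adjusted p = 0.338). Ndufa2 had the smallest p, at 0.94 ± 0.30. Ribosomal protein genes were higher with 35 of 41 positive, 0 higher and 0 lower over all genes by edgeR, and 2 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.58e-06, estimated-correlation adjusted p = 0.338). Rps20 had the smallest p, at 0.89 ± 0.24, and DESeq2 called Rps20 and Rps3. Interferon-stimulated genes were lower with 15 of 16 negative and none called by either adjustment (camera adjusted p = 0.0118, estimated-correlation adjusted p = 0.338). Irf9 was at -0.93 ± 0.36, Usp18 at -1.25 ± 0.50 and Oasl2 at -0.95 ± 0.38. These 3 were named above for higher values in the same day 28 libraries, so a fall was partly expected from that choice. The NF-kB list, lower at day 28 above, shares those libraries in the same way. Progenitor fibroblast genes were lower with 17 of 23 negative, 1 called over all genes and 0 higher and 3 lower adjusted over the list alone (camera adjusted p = 3.13e-05, estimated-correlation adjusted p = 0.338). Cd34 was followed by Clec3b, which DESeq2 called, at -0.67 ± 0.21 and Cd55 at -0.88 ± 0.30. The immediate-early list was lower with 18 of 25 negative, 0 higher and 0 lower over all genes by edgeR, and 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0194, estimated-correlation adjusted p = 0.440). Dusp1, which DESeq2 called, had the smallest p, at -0.79 ± 0.20.

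Genes followed throughout were not called by edgeR from day 28 to the end stage, while DESeq2 called Saa3, given above. Log2 fold changes of the others were 2.17 ± 0.93 for Ccl2, 1.71 ± 0.86 for Il6, 1.32 ± 0.48 for Cd74, 0.66 ± 0.48 for Acta2 and 0.79 ± 0.46 for Tgfb1. They were 0.43 ± 0.38 for Col1a1, 0.22 ± 0.27 for Cxcl12, -0.57 ± 0.94 for H2-Ab1 and -0.81 ± 0.36 for Pdgfra. An unadjusted p under 0.05 was reached by 581 genes. Among tested genes 3.11% had no overlap, against 1.59% by chance. The authors' deposited table holds 27 higher and 6 lower genes at an adjusted p under 0.05. Higher and lower counts were 5 and 0 without end stage replicate 4, 7 and 0 without day 28 replicate 3, 10 and 0 without day 28 replicate 4, 44 and 9 without end stage replicate 3, 35 and 2 without end stage replicate 2, 14 and 0 without end stage replicate 5, 16 and 0 without day 28 replicate 2, 12 higher without day 28 replicate 1, 13 higher without day 28 replicate 5 and 2 lower without normal replicate 1, and lists called higher became 3 without day 28 replicate 5. The TGF-beta call was lost without day 28 replicate 3, 4 or 5 or end stage replicate 4 or 5, the chemokine call without day 28 replicate 3 or 5 or end stage replicate 4 or 5, and the immediate-early call without day 28 replicate 1, 2 or 5 or end stage replicate 2 or 3. The interferon call was lost without day 28 replicate 3, the NF-kB call without end stage replicate 5 and the oxidative phosphorylation call without day 28 replicate 5. Other settings gave 64 and 23 with the within-group component as a covariate, 43 and 13 with DESeq2, 13 and 2 with limma-voom, 46 and 7 at the authors' thresholds, 43 higher and 12 lists higher without a filter, 9 and 0 with the shallow libraries left out, 35 and 5 with the immediate-early sum as a covariate, 4 lower with the replicate block and 0 lower with the 2 groups alone or a stricter filter.

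Across the 4 groups, 41 genes differed at any stage in the joint test of the 3 stages (edgeR, Benjamini-Hochberg). F2r had the smallest adjusted p (2.24e-05), followed by Col8a1 (6.83e-05) and Cxcl14 (0.000105). Among the genes followed throughout, the joint test called Cd74 (adjusted p = 0.0179) and Saa3 (0.0333). The count of 41 fell to 26 without day 7 replicate 3, to 26 without end stage replicate 5 and to 12 without end stage replicate 4. Other settings gave 97 with the within-group component as a covariate, 81 with DESeq2, 105 with limma-voom, 96 without a filter and 10 with thinning. The day 7 and end stage comparisons shared 1 called gene in the same direction, Gm4366. Simulated unchanged groups, compared with 1 set of simulated normal libraries, shared 0. In these simulations every library, the normal ones included, was redrawn around 1 common mean per gene. Independent lists would share 0.0064 higher and 8e-04 lower, and 0 were shared with the normal libraries split. The shared gene was lost, for 0 shared, without any 1 of the 16 libraries named at day 7. Over all genes the correlation of their log2 fold changes was 0.401, against 0.474 in the simulations, and the covariance was 0.0766 against 0.0778. For day 7 and day 28 the correlation was 0.332 against 0.465 and the covariance 0.0657 against 0.079. For day 28 and the end stage they were 0.322 against 0.43 and 0.079 against 0.0781. With separate normal libraries for each comparison, the correlations ran from −0.108 to 0.136, −0.242 to 0.072 and −0.077 to 0.133, in the same order. Genes are not independent replicates in this correlation.

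Cells other than fibroblasts were followed by marker counts summed as CPM of each library total. Summed macrophage and monocyte markers were 950.4 ± 407 in normal (SD, n = 5), 857 ± 402 at day 7, 979.6 ± 277 at day 28 and 1412 ± 217 at the end stage (SD, n = 4), where they moved with the complement and MHC class II lists. Against normal the macrophage sum gave a two-sided exact permutation p of 0.103 and an adjusted p of 0.472. In several libraries most of it was 1 gene, Apoe, which was at 1156 CPM in normal replicate 1, where the sum was 1209.5. In end stage replicate 3 Apoe was at 1599 CPM and the sum at 1627.8. Apoe levels are scaled by TMM and sums by library total. C1qa and C1qb belong to both this sum and the complement list, so part of that shared movement was built in. Globin and other erythrocyte genes were at 100.3 ± 39.6 in normal (SD, n = 5), 288 ± 148 at day 7, 179 ± 122 at day 28 and 734 ± 628 at the end stage. The exact permutation p was 0.00794 at day 7, the smallest that 5 against 5 libraries allow, with an adjusted p of 0.386. Epithelial and ID8 carcinoma markers were at 241 ± 53.6 in normal and 281 ± 147 in end stage libraries (exact permutation p = 0.857). Krt7, Krt8, Krt18, Krt19, Wt1 and Muc16 of this list are also mesothelial markers. The mesothelial sum was 587 at the end stage against 928 in normal libraries. A rise of carcinoma transcripts could therefore be hidden, and this sum does not exclude them. At the end stage against normal, the sums were 115 ± 29.3 against 94.4 ± 35.7 for B and plasma cells, 207 ± 98.8 against 126 ± 35 for adipocytes and 259.7 ± 117 against 239 ± 58.8 for Schwann and neural cells. T and NK cell markers, of which the table holds 1 gene, were at 5.90 ± 10.6, or 0.7 without end stage replicate 2, against 0.900 ± 1.40. Neutrophil and mast cell markers, of which it holds 2, were at 1.10 ± 1.30 against 4.90 ± 4.90. None of the 85 sums was called after adjustment (lowest adjusted p = 0.386), but with a smallest possible p of 0.00794 no sum could have been called on its own, so this says little about the absence of differences. Of the sex-linked list the table holds Xist alone, too low to be tested, at 14.2 ± 10.8 CPM (SD, n = 5) in normal and 8.51 ± 8.72 CPM (SD, n = 4) in end stage libraries.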

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

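Chosen after the result was seen were the tests of end stage replicate 4, of the immediate-early response and of the mural and mesothelial markers, while the tests by thinning and by GC content were written before their results.

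A library lay far from the others of its group in 10 of 84 groups of values, where chance marks about 1 in 20 groups. End stage replicate 4 had 2449339 total counts against 434324 in the next library, a Col8a1 level of 513 CPM against 164, a Ccn2 level of 2631 CPM against 596, and summed adipocyte markers of 354 CPM against 173. End stage replicate 5 had an immediate-early sum of 36673 CPM against 25348. End stage replicate 2 had a T and NK cell marker level of 21.7 against 2, from the 1 gene of that list in the table. Normal replicate 1 had summed mesothelial markers of 1704 against 815. Day 28 replicate 4 had Serpina3n at 297 CPM against 175 and Slc16a3 at 37.8 CPM against 7.65. Tnfrsf11b was at 12.8 CPM in day 28 replicate 5 and at 0 in the other day 28 libraries.

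Of the genes given here that were called at the end stage against normal, 9 were also called against day 28, which flags a different change from normal at the 2 stages. Both tests use the same end stage libraries and the genes were picked by both calls, so the differences are those of the calls and no further test. The log2 difference was 3.24 for Col8a1, which was at 2.60 at the end stage and −0.64 at day 28 against normal, 2.79 for F2r, 2.78 for Slc16a3, 2.10 for Cthrc1 (1.43, not called, without end stage replicate 4, and against normal called in 4 of 19 fits with 1 library left out and with overlap between the groups) and 1.80 for Serpina3n. It was 1.60 for Cfb, 1.15 for Cxcl14, 1.15 for Eln and 1.03 for Bgn.

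The first pattern weighed was the set of 24 genes called at the end stage, where a change of the fibroblasts with tumour growth stays open. Without end stage replicate 4, the deepest library, the median log2 fold change of the 24 genes signed by direction was 1.48 (quartiles 1.05 and 1.93). It was 1.59 (1.37 and 2.28) with that library. All 24 kept their direction without it and 7 were called. As the genes were picked in the same libraries, the median was likely to hold, so this is weak evidence against that library as the whole cause. With the immediate-early sum as a covariate the median was 1.64 (quartiles 1.39 and 2.06), though 1 gene was called, with a median SE of single genes of 0.46 against 0.34. The genes were picked in the same libraries, and Fosb, 1 of the 24, is part of the covariate. This test therefore cannot settle the part of the immediate-early response, which stays open. More mural and smooth muscle cells among the sorted cells stay open as a candidate explanation of part of the pattern. The weighted mean of the 6 markers was 0.65 ± 0.15, below the 1.59 of the called genes, with a chi-square heterogeneity p of 0.0512 across markers, near the threshold. That SE and p take the markers as independent, so they do not show 1 common change. Acta2 and Pdgfrb also belong to other lists, and the sort for Col1a1-driven fluorescence would remove mural cells that lack Col1a1.

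The second pattern was the fall of mesothelial markers. At day 7 the weighted mean of the 11 markers was −0.78 ± 0.14, with a chi-square heterogeneity p of 0.885. This SE and p take the markers as independent, but all were measured in the same libraries, with an estimated correlation of 0.368. The SE is therefore too small, and the high p does not show 1 shared change. Fewer mesothelial cells among the sorted cells may explain the fall, but this test cannot decide it. At the end stage the weighted mean was −0.69 ± 0.15, with the same limit, and the chi-square heterogeneity p was 0.0504, near the threshold. Members ran from −1.86 to 0.93, so that explanation is weaker there. Without normal replicate 1, whose summed markers were 1704 against a mean of 733 in the other normal libraries, the list stayed called at day 7 (camera adjusted p = 0.00569) but not at the end stage (0.0966), so that library may carry part of the fall. The sort for Col1a1-driven fluorescence would remove mesothelial cells that lack Col1a1, and lower expression of these genes in the sorted cells was not tested.

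The third pattern was the component along which 10 libraries lay below 0 and 9 above within the groups. That every group had libraries on both sides follows from the removal of the group means. After thinning to 66061 counts, 19 of 19 libraries kept their side, which argues against the counting error of shallow libraries as the cause. Thinning cannot test a composition that goes with depth, which stays open. In normal libraries the totals were 186032 and 268295 below 0 and at least 304626 above. Day 7 libraries also divided by total, but day 28 and end stage libraries did not. Over all libraries the component had a Spearman correlation of 0.31 with total counts. The loading of genes correlated with the GC content of their transcripts (Spearman −0.366 across genes, which are not independent replicates), and genes lower in the component had a median GC content of 55% against 49.7%, so a bias by GC content may contribute. Higher with the component by camera at the preset correlation were the immediate-early, chemokine, matrix structure, NF-kB, ECM enzyme and unfolded protein lists (adjusted p = 0.014 each). The cytosolic ribosomal protein list was higher too (0.0449). The component was computed from the same counts, in part from genes of these lists, so those p-values are not an independent test. No label gives a batch that follows the component, and no biological explanation was tested.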

How the results depend on the processing

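The 6 alternatives added after the data had been seen were the libraries under 150000 counts left out, thinning, the authors' thresholds, the removal of Rn18s-rs5, and the immediate-early sum and the within-group component as covariates, and the others were planned. The pseudocount settings planned for normalized values were not run, since the deposited values are counts. Counts within 1.5 times those of the report are not repeated. DESeq2's size factors in edgeR, a log2 fold change of at least 1 and the removal of Rn18s-rs5 kept every count of genes within that bound, and the first and last of these every count of lists. Below, each sentence gives the counts outside it, and the cause was not tested unless stated.

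Of the settings chosen beforehand, scaling by library size alone gave 0 higher and 0 lower genes at day 7 and 0 genes shared by day 7 and end stage. Without a filter on low counts, the analysis gave 1 higher and 2 lower genes at day 7, 9 higher and 2 lower lists at day 7, 29 higher genes at the end stage, 18 higher lists at the end stage, 4 higher lists from day 7 to day 28, 43 higher genes from day 28 to the end stage, 12 higher lists from day 28 to the end stage and 96 genes at any stage. Signs turned for Saa3 at day 28 (log2 fold change -0.017 instead of 0.033) and Cxcl12 from day 7 to day 28 (log2 fold change -0.012 instead of 0.092). A stricter filter on low counts gave 5 higher lists from day 7 to day 28 and 0 lower genes from day 28 to the end stage. DESeq2 gave 2 lower genes at day 7, 32 higher and 16 lower genes at the end stage, 43 higher and 13 lower genes from day 28 to the end stage and 81 genes at any stage. Opposite signs were found for Acta2 at day 28 (log2 fold change 0.029 instead of -0.040) and Saa3 at day 28 (log2 fold change -0.20 instead of 0.033). limma-voom with quality weights gave 7 lower genes at day 7, 32 higher and 18 lower genes at the end stage, 23 higher and 9 lower genes from day 7 to day 28, 13 higher and 2 lower genes from day 28 to the end stage, 105 genes at any stage and 3 genes shared by day 7 and end stage. Of the opposite sign were H2-Ab1 at day 7 (log2 fold change -1.65 instead of 0.81), Acta2 at day 28 (log2 fold change 0.10 instead of -0.040), Il6 at the end stage (log2 fold change -0.11 instead of 0.32) and Ccl2 at the end stage (log2 fold change -0.047 instead of 0.21). A fit of the 2 compared groups alone gave 0 higher and 0 lower genes at day 7, 2 lower genes at the end stage, 0 lower genes from day 28 to the end stage and 0 genes shared by day 7 and end stage. The cause was not tested.

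The replicate block, with the replicate number as a term, gave 0 higher and 0 lower genes at day 7, 10 lower genes at the end stage, 3 higher lists from day 7 to day 28, 4 lower genes from day 28 to the end stage and 0 genes shared by day 7 and end stage. Opposite signs were found for Acta2 at day 28 (log2 fold change 0.050 instead of -0.040), Saa3 at day 28 (log2 fold change -0.39 instead of 0.033) and Ccl2 at the end stage (log2 fold change -0.13 instead of 0.21). The camera test with an estimated correlation gave 0 higher and 0 lower lists at day 7, 0 higher and 0 lower lists at day 28, 0 higher and 0 lower lists at the end stage, 0 lower lists from day 7 to day 28 and 0 higher and 0 lower lists from day 28 to the end stage. The labels describe separate mice, and 6 of 19 libraries correlated best with a library of their own number, so the numbers were not read as pairs. The cause of the changes with the block was not tested.

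Of the added settings, leaving out the 3 libraries under 150000 counts gave 0 higher and 0 lower genes at day 7, 3 higher lists from day 7 to day 28, 9 higher and 0 lower genes from day 28 to the end stage and 0 genes shared by day 7 and end stage. Opposite signs were found for Col1a1 at day 28 (log2 fold change -0.24 instead of 0.24), Tgfb1 at day 28 (log2 fold change -0.15 instead of 0.13) and Tgfb1 from day 7 to day 28 (log2 fold change -0.075 instead of 0.21). Thinning to at most 200000 counts per library gave 0 higher and 0 lower genes at day 7, 2 higher and 2 lower lists at day 28, 12 higher and 2 lower genes at the end stage, 1 higher list from day 7 to day 28, 10 genes at any stage and 0 genes shared by day 7 and end stage. Opposite signs were found for Acta2 at day 28 (log2 fold change 0.11 instead of -0.040). Use of the authors' thresholds gave 30 higher and 12 lower genes at the end stage and 46 higher and 7 lower genes from day 28 to the end stage. The immediate-early sum as a covariate gave 0 higher and 0 lower genes at day 7, 0 higher and 0 lower lists at day 28, 1 higher and 0 lower genes at the end stage, 6 higher and 2 lower lists at the end stage, 35 higher and 5 lower genes from day 28 to the end stage and 0 genes shared by day 7 and end stage. The sign was opposite for the immediate-early list at the end stage (now higher, camera adjusted p = 0.611 instead of 1.22e-06), the immediate-early list from day 28 to the end stage (now higher, camera adjusted p = 0.407 instead of 0.0194), Acta2 at day 28 (log2 fold change 0.041 instead of -0.040) and H2-Ab1 at the end stage (log2 fold change -0.086 instead of 0.91). The within-group component as a covariate, estimated from the same counts, gave 49 higher and 23 lower genes at the end stage, 4 higher lists from day 7 to day 28, 64 higher and 23 lower genes from day 28 to the end stage and 97 genes at any stage. Signs turned for Acta2 at day 28 (log2 fold change 0.16 instead of -0.040). The immediate-early list is the source of its own covariate, so its change of sign follows from the construction. Fewer counts or samples were available in the first 2 of these, and the cause of the other changes was not tested.

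With each of the 19 libraries left out in turn, the counts ran as follows. There were 0 to 2 genes higher, 0 to 1 genes lower, 3 to 7 lists higher and 1 to 2 lists lower at day 7. There were 0 genes higher, 0 to 1 genes lower, 2 to 5 lists higher and 0 to 4 lists lower at day 28. There were 3 to 33 genes higher, 0 to 10 genes lower, 7 to 13 lists higher and 3 to 5 lists lower at the end stage. There were 0 genes higher, 0 genes lower, 0 to 4 lists higher and 2 to 8 lists lower from day 7 to day 28. There were 5 to 44 genes higher, 0 to 9 genes lower, 3 to 9 lists higher and 2 to 4 lists lower from day 28 to the end stage. The range was 12 to 49 for genes at any stage and 0 to 1 for genes shared by day 7 and the end stage. Leaving out a library also lowers the number of samples, and the cause was not tested further.

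Log2 fold changes of genes followed throughout that changed sign when a library was left out, none of them called, had these ranges. The range at day 7 was -0.34 to 0.066 for Tgfb1, -0.47 to 0.041 for Pdgfra and -1.16 to 0.11 for Saa3. The range at day 28 was -0.28 to 0.26 for Pdgfra, -0.25 to 0.68 for Acta2, -0.40 to 0.73 for Saa3, -0.16 to 0.47 for Tgfb1, -0.23 to 0.51 for Col1a1 and -0.21 to 0.61 for Cd74. The range at the end stage was -1.01 to 0.63 for Ccl2 and -0.38 to 1.34 for Il6. The range from day 7 to day 28 was -0.015 to 0.39 for Cxcl12, -0.58 to 0.10 for Col1a1, -0.088 to 0.54 for Tgfb1 and -0.18 to 1.35 for H2-Ab1. The range from day 28 to the end stage was -0.80 to 0.29 for H2-Ab1. Of the 24 genes called at the end stage, Cxcl14, F2r and Col8a1 were called in all 19 of these fits and the log2 fold change of each of the 24 kept its sign wherever it was fitted, which left out Runx1 without day 28 replicate 4. Power was limited in all comparisons. In simulated data of the same depths, group sizes and spread, 18% to 24% of genes changed 2-fold and 73% to 86% of genes changed 4-fold were recovered. Between 5 and 10 unchanged genes were also called in each comparison. Depth was not varied alone, so the limit cannot be put down to depth. Genes were drawn independently, without the within-group component, so real recovery may differ. With the complement list raised as well, 104 to 123 genes were called per simulated comparison, against at most 24 in the real ones. The adjustment is more lenient when more genes change, so recovery may be overstated for data with few changes.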

Other observations

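The tests in this part were planned before their results, and the comparison of end stage with day 7 was added after the data were seen.

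Other splits of the libraries were set against the counts, 100 for each result with the real one included. Each result was judged alone, without adjustment over the results, so a low count makes chance less likely but does not exclude it. At day 7, 3 splits called as many genes as the real one (3), which by this count alone made chance less likely. Other values leave chance open there: 208 genes reached an unadjusted p under 0.05 against 299 expected, 0.79% of genes had no overlap, the share chance gives, and 0 genes were called in 16 of 19 fits with 1 library left out. The highest other split called 250, which points to a structure of the samples, and it placed normal replicates 1 and 3 and day 7 replicates 1, 2 and 5 together. For the gene lists at day 7, 11 splits called as many as the real one (6, highest other 10), so chance was not excluded. At day 28 all 100 splits called as many genes as the real 0, the highest other 47, in a split that set normal replicates 1 and 3 and day 28 replicates 1, 3 and 5 apart and again points to a structure of the samples, and for the lists 6 splits reached the real 8, the highest other 11, so chance was not excluded. At the end stage 2 splits gave as many genes as the real one (24), so chance was less likely, but the highest other called 164, several times the real count. That split set normal replicates 1 and 3 and end stage replicates 2 and 3 against the rest, all 4 below 0 on the within-group component, which points to a structure of the samples. For the end stage lists, 2 splits reached the real 14, the highest other 14. Camera with an estimated correlation called 0 lists there, so chance was not excluded. From day 7 to day 28 all 100 splits called as many genes as the real 0, the highest other 5, and for the lists 24 reached the real 5, the highest other 11, so chance was not excluded. From day 28 to the end stage, 1 split, the real one, reached 24 genes, the highest other 8, so chance was unlikely. For the lists 8 splits reached the real 9, the highest other 12, so chance was not excluded. For genes at any stage, 1 split, the real one, reached 41, the highest other 8, so chance was unlikely.

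End stage against day 7, outside the comparisons of the report, called 24 genes higher and 4 lower with edgeR, among them Col8a1, F2r, Cxcl14, Slc16a3, Lox, Cd74 and Saa3 higher and Cdkn1a and Plpp3 lower, and the authors' deposited table holds 31 higher and 9 lower at an adjusted p under 0.05. Within groups, 36 pairs of libraries differed by a chi-square per degree of freedom of 2.51 to 12.7, above that of repeated counts of 1 sample.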
